A study of Mus musculus with 12 samples.

How the data were processed

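RNA-seq was measured in 3 WT and 3 cKO-labelled libraries of mouse Th2 cells, and ATAC-seq in 3 and 3 others. Groups follow the labels. The labels list STAR, RSEM 1.3.3, DESeq2, edgeR, Bowtie2 2.3.5.1 and HOMER 4.11 for all samples, without their settings, and the mm10 build. The deposited RNA table holds a signal: the authors' normalized counts per gene, which are not whole numbers (0.18% of values above 0 lie within 0.001 of a whole number), so whole reads were not recovered and the raw depth is unknown. The authors' fold change is a log2 value, cKO over WT, smaller in size than the log2 ratio of group means for 99.8% of the 11943 genes with a mean of at least 50. Its deposited p-value and adjusted p-value are the authors' own; 9263 genes have an adjusted one. The deposited ATAC files are HOMER peak lists, 1 per library. Per the file headers the tag count of each peak is a signal scaled to 10000000 tags per library, the peak score is a score in unscaled tags, and the clonal fold change is a ratio of observed to expected positions. Peaks were called at a Poisson p-value threshold of 0.001, and at most 1 tag per bp was considered.

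Genes with a mean of at least 10 normalized counts were tested with limma 3.58.1 in R 4.3.3 (eBayes with a mean-variance trend) on log2 of the value plus 1, with Benjamini-Hochberg adjustment and a threshold of 0.05. Of 35 gene lists fixed before the data were examined, the 32 with at least 5 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. fry tests whether a list's genes move one way on balance and does not compare them with other genes. Counts adjusted over the list alone are given beside counts over all genes. Named genes were Nfe2l2, up to 12 rises and 12 falls with a mean of at least 50 and no overlap between groups, up to 4 members with the smallest p of each list described, and a fixed set of Th2 and NRF2 genes. Predicted genes, Xist and Y-linked genes were left out of the rises and falls; 1 predicted gene, Gm15454, was among the 6 that rose. Genes and regions outside this rule are said to be so where named.

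Peaks sharing at least 1 bp were merged with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6. The height of a region in a library was the tag count of its highest peak. At regions with a peak in all 6 lists, log2 of height plus 1 was tested with limma after subtracting each library's median. The 4 scalings were this one, no subtraction, quantile normalization and cyclic loess. Regions were placed on the GRCm38 gene table, which gives no strand, so both ends of each gene were used within 1 kb where the plan named the gene's start. Of the RNA table's genes 82.8% matched that table by symbol. Peak numbers were compared by an exact permutation test over 20 arrangements, and ATAC changes at RNA-changed genes by 100000 permutations over genes (scipy 1.17.1). Figures were drawn with matplotlib 3.10.9.

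The same fits were tested on simulated data. With 100 genes changed by 1 on the log2 scale, 15 were recovered for RNA and 48 regions for ATAC height; with a change of 2, 65 and 93 were, all with the right sign. Alternatives were other pseudocounts, filters, normalizations and variance models, the replicate number as a block, each library left out, the authors' adjusted p, other peak thresholds and overlaps, and 5 kb in place of 1 kb. The labels do not say whether the replicate number pairs the libraries. Correlations of same-number WT and cKO-labelled libraries around their group means were 0.12, 0.21 and -0.06 for RNA and -0.03, -0.01 and 0.01 for ATAC. Those of different numbers ran from -0.27 to 0.22 for RNA and from -0.02 to 0.03 for ATAC. With 3 libraries per group such correlations cannot rule pairing out. Tests on whole reads were left out because the table does not give them.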

Results

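Mouse Th2 cells, the helper T cells that make the cytokines of allergic inflammation, were profiled by RNA-seq and by ATAC-seq, which reads where DNA is open to a transposase. The labels give 2 genotypes, WT and cKO (conditional knockout), with 3 libraries per genotype in each assay, 12 in all. The series title names NRF2, the transcription factor encoded by Nfe2l2 that switches on antioxidant genes, but the labels do not say which gene or which part of it was deleted, so the groups are called WT and cKO-labelled here. Totals of the RNA libraries ran from 6431081 to 7372007 normalized counts over 25700 genes. ATAC libraries held 13149952 to 18327127 tags, of which 25.22% to 38.28% lay in peaks. The comparison of the genotypes asks what changes in the transcripts and in the open chromatin of these cells.

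The largest RNA change among the named genes past the threshold was the fall of Prcd, a photoreceptor disc gene, from 611.6 ± 71.0 normalized counts in WT to 81.4 ± 13.3 in cKO-labelled libraries (SD, n = 3 each). That is 7.46-fold lower (log2 change -2.90, SE 0.229, adjusted p = 0.00023). Ccl1, a chemokine made by Th2 cells, fell 3.02-fold, from 468.9 ± 118.9 to 156.7 ± 47.5 (adjusted p = 0.0438). The genes that rose were Hspa1a and Hspa1b, which encode inducible heat shock proteins, the activation marker Cd83, the immediate early gene Jun, and Nfe2l2 itself. Hspa1a rose 3.64-fold from 350.4 ± 163.9 to 1179.5 ± 126.8, Cd83 2.54-fold from 551.4 ± 86.0 to 1398.8 ± 185.6, and Jun 2.09-fold from 612.2 ± 68.9 to 1285.1 ± 199.4.

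Of 18074 genes tested, 37 passed an adjusted p of 0.05 in limma, 6 higher and 31 lower in the cKO-labelled libraries, and 2188 had an unadjusted p under 0.05. After Prcd and Ccl1, the largest falls were those of the small RNAs Bc1 (log2 change -1.57) and Rpph1 (-1.53), Lockd (-1.52), the mitotic kinesin Kif20b (-1.42), the RNA polymerase subunit Polr2l (-1.35), Dnajc15 (-1.26), the centromere protein Cenpw (-1.17), the nucleotide kinase Nme1 (-1.16), the complex I subunit Ndufa2 (-1.12) and the RNA-binding Lsm6 (-1.09). The authors' own table put 526 genes past 0.05, 165 higher and 361 lower, and held 34 of these 37. The count of 37 moved with single libraries: it was 84, 1 and 5 without WT replicate 1, 2 and 3, and 3, 150 and 3 without cKO replicate 1, 2 and 3. After quantile normalization 17 genes were higher and 16 lower, and with sample quality weights, which gave cKO replicate 1 a weight of 7.43 and the other libraries 0.44 to 1.12, 943 and 840. Of the 21 named genes that passed, Y-linked genes aside, Prcd was the 1 that passed under every alternative setting, each left-out library included.

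Nfe2l2 (chromosome 2, 75675513 to 75704663, mm10) was higher, not lower, in the cKO-labelled libraries. Its normalized counts were 169.92, 155.3 and 147.37 in WT and 452.83, 326.42 and 391.53 in the cKO-labelled libraries, a 2.45-fold rise (log2 change 1.29, SE 0.22, adjusted p = 0.0438). The adjusted p was 0.0977 without WT replicate 2, 0.216 without WT replicate 3, 0.324 without cKO replicate 1 and 0.216 without cKO replicate 3, with log2 changes of 1.18 to 1.42 over all 6 such fits; it was 0.0748 with trimmed mean rescaling and 0.446 without the mean-variance trend. The table gives 1 value per gene, so transcripts with and without a deleted part were not told apart.

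**Figure D1:**
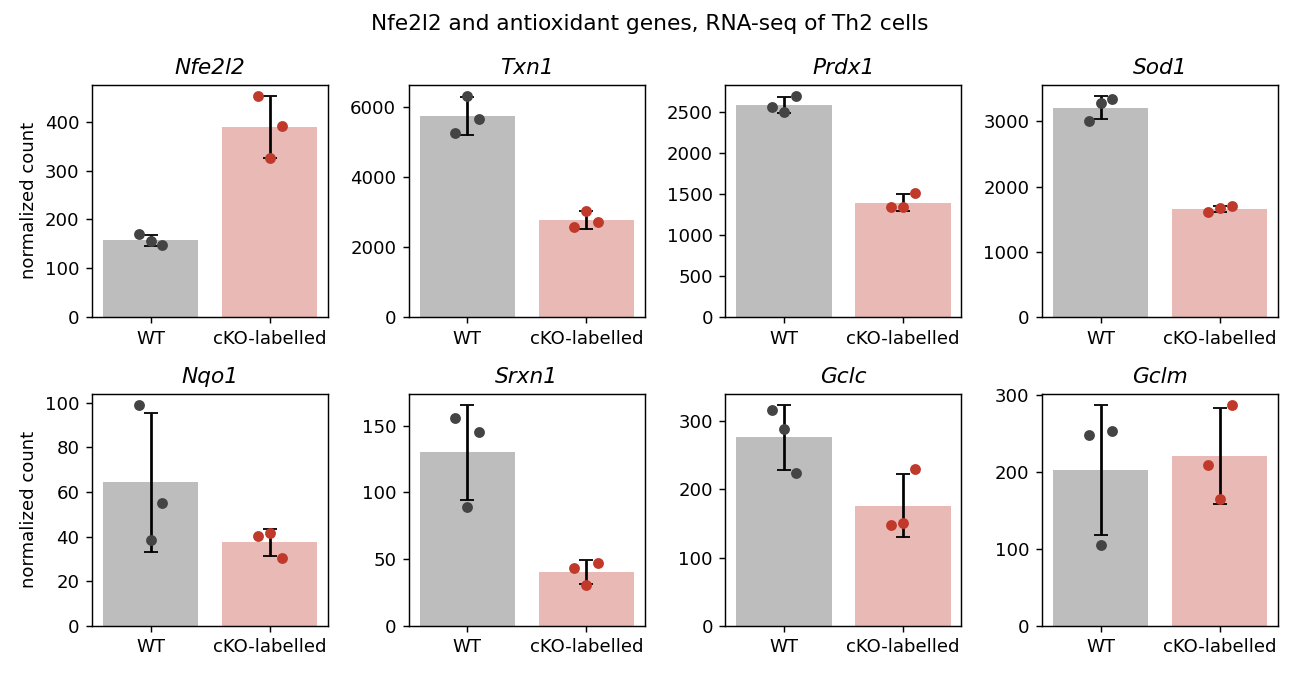
Normalized counts of Nfe2l2 and 7 antioxidant genes in each RNA library; bars are group means, error bars SD (n = 3), points libraries. All 3 cKO-labelled values lie above all WT values for Nfe2l2 and below them for Txn1, Prdx1 and Sod1.

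Antioxidant genes were mostly lower in the cKO-labelled libraries. Txn1, which encodes thioredoxin, fell 2.07-fold from 5740.3 ± 538.0 to 2769.9 ± 245.9 (adjusted p = 0.0144), the superoxide dismutase gene Sod1 fell 1.93-fold from 3208.5 ± 179.8 to 1659.2 ± 45.9 (adjusted p = 0.0221), and the peroxiredoxin gene Prdx1 fell 1.86-fold from 2588.2 ± 99.3 to 1395.6 ± 99.7 (adjusted p = 0.0421). None of these 3 passed without WT replicate 2, WT replicate 3, cKO replicate 1 or cKO replicate 3 (adjusted p of 0.0596 to 0.133 for Txn1, 0.079 to 0.215 for Sod1 and 0.0832 to 0.236 for Prdx1). In the list of NRF2 target genes, 2 of 35 tested members fell (Txn1 and Prdx1), none rose and 25 had negative log2 changes, with a median of -0.22. camera called the list lower (adjusted p = 0.0022), but the adjusted p was 0.637 with an estimated correlation and 0.0717 without WT replicate 1, and the fry adjusted p was 0.218. Adjusted over the list alone, 4 members were lower and 1 higher. The members usually used to read NRF2 activity did not pass in limma. Srxn1 had a log2 change of -1.65 (adjusted p = 0.082), Nqo1 -0.67 (0.571), Gclc -0.67 (0.312), Txnrd1 -0.68 (0.187) and Gclm 0.20 (0.862). Values of Srxn1 and Txnrd1 did not overlap between groups, while those of Nqo1, Gclc and Gclm did. Txnrd1 did pass in the authors' own table, as lower (authors' adjusted p = 0.0386). Gclc and Gclm did not pass there (0.156 and 0.886), and that table gives no adjusted p for Srxn1 or Nqo1. Of the NRF2 list, 3 members passed there as lower and 1 as higher. In the list of other antioxidant enzymes 3 of 23 members fell (Txn1, Sod1 and Prdx1), 20 had negative changes and the median was -0.38. Its camera adjusted p was 1.51e-09, its adjusted p with an estimated correlation 0.0669 and its fry adjusted p 0.00337. Adjusted over the list alone, 8 were lower.

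Nuclear-encoded genes of oxidative phosphorylation, the respiratory chain and ATP synthase, were lower as a group. Mitochondrially encoded genes, among them other subunits of the same complexes, took 2.48%, 3.35% and 2.15% of the total in WT and 3.95%, 2.91% and 4.47% in the cKO-labelled libraries. Of 75 members 69 had negative log2 changes, the median was -0.41 and 1 member, Ndufa2, fell past the threshold over all genes, while 35 were lower adjusted over the list alone. The camera adjusted p was 1.22e-25, the adjusted p 0.157 with an estimated correlation, and the fry adjusted p 0.0215. The next members were Ndufa5 (log2 change -1.13, adjusted p = 0.065), Atp5e (-1.02, 0.065) and Ndufc1 (-0.95, 0.0676). Genes of the cell cycle had a median of -0.42 over 40 members, 36 of them negative, and 0 passed over all genes while 6 were lower adjusted over the list alone. Ube2c had a log2 change of -0.84 (adjusted p = 0.0772) and Birc5 -0.77 (0.0977). For this list the camera adjusted p was 9e-10, the adjusted p 0.637 with an estimated correlation, and the fry adjusted p 0.356. Glycolysis genes had a median of -0.19 over 23 members, of which 0 passed and 4 were lower adjusted over the list alone. Their camera adjusted p was 0.015, and 0.786 with an estimated correlation, 0.191 after quantile normalization, 0.196 without WT replicate 1 and 0.321 without cKO replicate 2, and the fry adjusted p was 0.547. Log2 changes also went with gene length: their median ran from -0.03 in the fifth of genes with the shortest span to 0.15 in the fifth with the longest; the first held 11 and the last 0 of the genes that fell. The 31 genes that fell had a median span of 8.7 kb, against 20.1 kb for all tested genes. Libraries of a group differed in this: Spearman's rho with span across genes, which are not independent replicates, was -0.032, -0.113 and -0.096 in WT and 0.1, -0.006 and 0.107 in the cKO-labelled libraries. In 10000 random lists matched on expression and span, the lowest median was -0.30 against -0.41 for oxidative phosphorylation, and -0.26 against -0.42 for the cell cycle. The other called lists that were lower had medians near the low end of their random lists: glycolysis lay at percentile 1.7 (median -0.19, lowest random median -0.30), NRF2 targets at 0.1 (-0.22, -0.29), other antioxidant enzymes at 0.0 (-0.38, -0.42) and the Th17 list at 0.4 (-0.43, -0.80). Members of the random lists were drawn independently. The estimated correlation between genes was 0.11 for oxidative phosphorylation, 0.34 for the cell cycle and 0.42 for glycolysis. Random medians spread too little for such lists, so a place outside their range does not test against chance.

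Immediate early and heat shock genes were the 1 called list that was higher (camera adjusted p = 0.00055, and adjusted p = 0.637 with an estimated correlation). Of 23 members 3 rose (Hspa1a, Hspa1b and Jun), 19 had positive log2 changes and the median was 0.33, while Hsp90aa1, a chaperone gene of the same list, had a log2 change of -0.63 (adjusted p = 0.0681). The fry adjusted p was 0.356, and the highest median of 10000 matched random lists was 0.21. Members of those lists were drawn independently, while the estimated correlation in this list was 0.35. Adjusted over the list alone, 7 were higher and 2 lower.

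**Figure D2:**
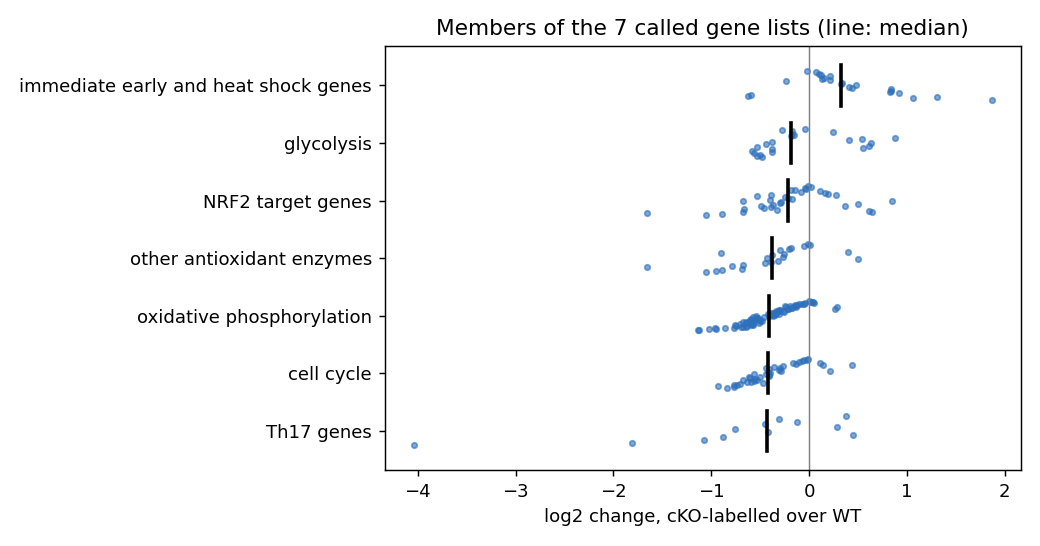
Log2 change, cKO-labelled over WT, of each tested member of the 7 lists that camera called; points are genes and the black line is the list's median. The medians run from -0.43 in the Th17 list to 0.33 in the immediate early and heat shock list.

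Th2 identity genes were not called as a group. Gata3, the factor that sets Th2 fate, was at 711.7 ± 37.5 in WT and 719.7 ± 114.0 in cKO-labelled libraries (log2 change 0.00, adjusted p = 0.995), with a sign that changed between settings. Il13 was at 810.1 ± 245.8 and 384.7 ± 58.3 (log2 change -1.04, adjusted p = 0.0834), Il9 had a log2 change of -2.74 (0.163), Areg of -1.17 (0.202) and Pparg of 0.95 (0.661). Il13 did pass in the authors' own table, as lower (authors' adjusted p = 0.00104). That table gives no adjusted p for Il9, Areg or Pparg. Il4 and Il5 were below the minimum mean, at 2.23 and 6.25. The list of 27 Th2 genes had a median of 0.00 and a mean of -0.20, and camera gave an adjusted p of 0.259. Ccl1 was its 1 member that fell, and 4 were lower adjusted over the list alone. The Th17 list had a median of -0.43 over 12 members with 0 past the threshold and 2 lower adjusted over the list alone. Il22 was at 23.3 ± 9.2 and 0.6 ± 1.0 (adjusted p = 0.129) and Ccl20 at 46.4 ± 10.0 and 13.3 ± 6.7 (0.182). Its camera adjusted p of 0.0331 became 0.637 with an estimated correlation, and 0.961 with a positive median of 0.08 among genes with a mean of at least 50, and its fry adjusted p was 0.131.

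Summed markers of other cell types were mostly lower in the cKO-labelled libraries by small amounts, and those of T cells were level. The summed T cell markers took 0.552% of the total in WT and 0.564% in cKO-labelled libraries. The ratio of cKO-labelled over WT sums was 0.987 for B cell markers, 0.924 for plasma cell markers, 0.858 for myeloid and dendritic markers, whose sums did not overlap between groups, 0.889 for neutrophil, 0.937 for eosinophil, basophil and mast cell, 0.835 for epithelial and stromal and 1.19 for erythroid markers, and 0.922 for markers of CD8 T, NK and gamma delta T cells. Transcripts of Y-linked genes differed fully: Ddx3y was at 131.9 ± 8.6 and Eif2s3y at 122.2 ± 5.1 in WT, and both were listed at 0 in every cKO-labelled library, while Xist was at 3699.9 ± 463.4 in WT and 5894.9 ± 1409.8 in cKO-labelled libraries (adjusted p = 0.152). Ddx3y and Eif2s3y are 2 of the 37 called genes, and 36 genes passed when X-linked and Y-linked genes were left out of the test. Ribosomal protein genes took 9.23%, 11.44% and 10.54% of the total in WT and 8.0%, 9.56% and 7.83% in the cKO-labelled libraries.

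Open chromatin was called at 66557 ± 7667 peaks per WT library and 58190 ± 5377 per cKO-labelled library, a difference larger than the SD of either group, with values that overlapped between groups (two-sided exact permutation test, p = 0.2, smallest possible p 0.1). The 6 peak lists merged into 114463 regions, of which 33531 had a peak in every library. Regions called in all 3 WT lists and no cKO-labelled list numbered 2839, against 321 the other way. Of the first, 128 (4.5%) lay within 1 kb of an end of a protein-coding gene, of the second 61 (19.0%), against 16.4% of all regions and 35.5% of those called in all 6 lists, which are longer (median 1497 bp, against 698 and 921 bp). The first and second were also low, with median heights of 10.5 and 9.4 tags per 10000000, against 33.2 for regions in all 6 lists. The lowest peak in the WT lists was at 5.28. Among the first was a region at the lower end of Ccl1 (chromosome 11, 82174614 to 82176319), and the highest lay inside Cntnap5b (chromosome 1, 100179988 to 100180497, 140.9 ± 39.7 tags per 10000000, n = 3 WT). The highest of the second lay inside Arhgap33os (chromosome 7, 30518398 to 30520825, 22.3 ± 13.5). With an equal number of top-scoring peaks from every list, 50 percent of the shortest list, the counts were 1022 and 825. With as many peaks as the whole shortest list they were 1975 and 520. The first was 5595, 4854 and 4806 without WT replicate 2, WT replicate 3 and cKO replicate 2, and the second 711, 496, 1289, 820 and 1166 without WT replicate 1, WT replicate 3 and cKO replicates 1, 2 and 3; fewer lists make the criterion looser.

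Peak height changed most at Cd4, the gene of the helper T cell co-receptor. The region over its higher-coordinate end (chromosome 6, 124879464 to 124889302) rose from 45.6 ± 6.4 tags per 10000000 in WT to 812.3 ± 24.2 in cKO-labelled libraries (log2 change 4.44, SE 0.105, adjusted p = 1.61e-11), and the next largest change of any region was 2.55 in size. These heights are those of the highest peak, which grows with peak length: the log2 change was 3.34 for the summed tags of the region and 1.93 for tags per kb of peak (adjusted p = 6.04e-06), which were 24.3 ± 5.0 in WT and 85.4 ± 1.5 in cKO-labelled libraries. WT libraries held 3 separate peaks over 4.07 ± 0.23 kb there, and each cKO-labelled library held 1 unbroken peak of 9.51 ± 0.13 kb. Cd4 RNA was at 1954.5 ± 276.4 and 3132.3 ± 996.4 (log2 change 0.63, adjusted p = 0.259). The other regions with the smallest p that rose lay at ends of Mpp5 (log2 change 1.23), Acin1 (1.11), Calr (1.14) and Ano10 (1.03). After quantile normalization these rises were smaller, at 0.50, 0.29, 0.34 and 0.28. Those that fell lay in Cd274, the gene of the ligand PD-L1 (chromosome 19, 29382093 to 29386461, from 92.3 ± 11.9 to 12.2 ± 2.0, log2 change -2.52), in Mctp2 (-1.73), 54804 bp from Cd44 (-1.40), in Ppp3cc (-1.94) and in Trim41 (-1.52). All 10 passed under each of 4 scalings, but none of the 5 that fell passed when tags were divided by peak length: Cd274 was then at -0.21, Ppp3cc at -0.18, and Mctp2, Cd44 and Trim41 turned to 0.31, 0.27 and 0.02. By the summed tags of the region all 5 stayed lower and past the threshold. The log2 changes were then -1.71 at Cd274, -0.53 at Mctp2, -0.6 near Cd44, -1.95 at Ppp3cc and -1.42 at Trim41.

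**Figure D3:**
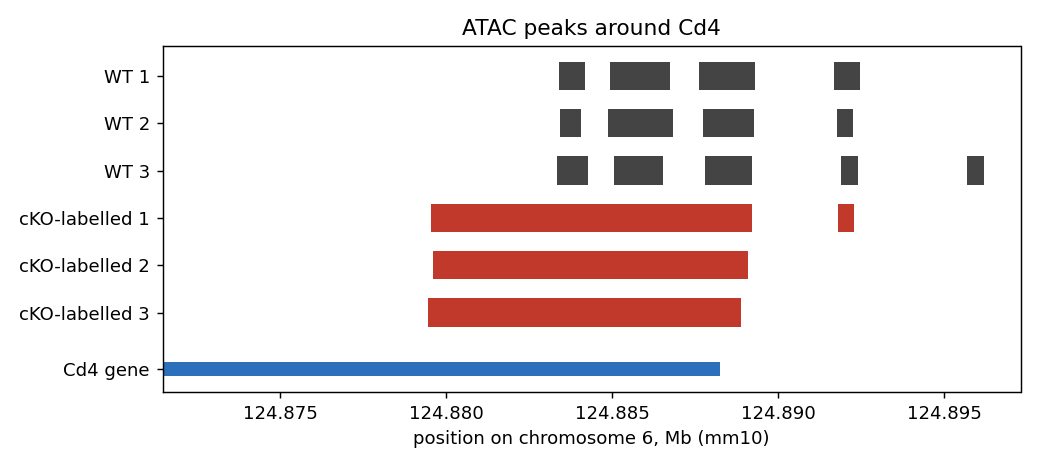
ATAC peaks of the 3 WT (grey) and 3 cKO-labelled (red) libraries along chromosome 6 in Mb, with the Cd4 gene in blue. WT libraries hold 3 peaks where each cKO-labelled library holds 1 peak of 9.51 ± 0.13 kb.

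Across the 33531 regions, 11223 passed the adjusted p of 0.05, 9387 higher (83.6%) and 1836 lower in the cKO-labelled libraries, and the direction of this total depended on the scaling. Without subtracting library medians 459 were higher and 3029 lower, after quantile normalization 1229 and 1452, and after cyclic loess 1373 and 1768. The median log2 change of all regions was 0.158 with the medians subtracted, -0.148 without and 0.022 after quantile normalization. With medians subtracted, the tallest of 10 equal groups of regions by height had a median change of 0.76 and the third lowest -0.17, and after quantile normalization all 10 medians lay from -0.07 to 0.06. A common direction was called under all 4 scalings for 346 regions that were higher and 749 that were lower, of which 265 and 224 were also called that way per kb of peak.

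**Figure D4:**
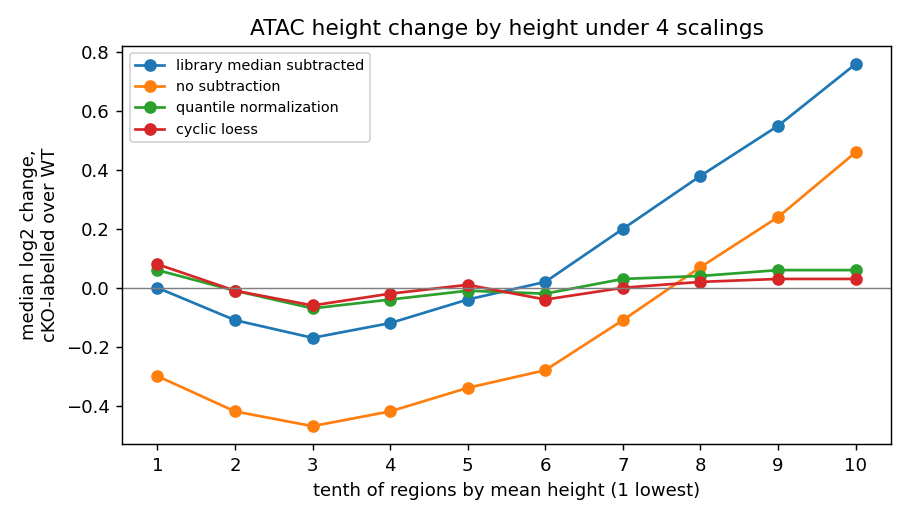
Median log2 change in ATAC height, cKO-labelled over WT, in 10 equal groups of the 33531 regions ordered by mean height, under 4 scalings. With library medians subtracted the tallest group is at 0.76, and after quantile normalization at 0.06.

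Among the genes named for RNA, the region at the higher-coordinate end of Nqo1, a classic NRF2 target, was lower in the cKO-labelled ATAC libraries under every alternative run. This region (chromosome 8, 107402803 to 107403994) fell from 41.3 ± 11.2 to 15.4 ± 2.7 (log2 change -1.04, SE 0.223, adjusted p = 0.00232), and its change was -0.72 per kb of peak (adjusted p = 0.00919). Ends of other NRF2 targets had positive changes with medians subtracted: 0.80 at Gclm (adjusted p = 0.000446), 0.49 at the lower-coordinate end of Srxn1 (0.00786), 0.47 at Gclc (0.0146) and 0.81 at Prdx1 (0.000115), which after quantile normalization were 0.19, 0.12, 0.06 and 0.42, none past the threshold. The higher-coordinate end of Srxn1 was at 0.08 (adjusted p = 0.827) and at -0.23 without subtraction. At Txn1 the change was 0.52 (adjusted p = 0.000921) and turned to -0.26 after quantile normalization, also past the threshold (adjusted p = 0.0397). Of 148 regions called in all 6 lists at named genes, 2 were higher (Cd4 and Fads2) and 2 lower (Nqo1 and Ptger2) under all 4 scalings. Of all 33531 regions 346 were higher and 749 lower, so falls were not more frequent at named genes. The region at the higher end of Nfe2l2 (chromosome 2, 75703132 to 75705717) was at 298.3 ± 71.8 and 409.6 ± 18.6, with a log2 change of 0.79 that was 0.49 without subtraction, 0.00 after quantile normalization and -0.02 after cyclic loess. At Il13 the change was 0.88 with medians subtracted and 0.26 after quantile normalization (adjusted p = 0.138), and at Gata3 it was 0.01 and -0.15.

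ATAC height at the ends of genes that changed in RNA was compared to ask whether both assays move together. On average it was higher in cKO-labelled libraries for genes that rose and for genes that fell. The mean log2 change in height was 0.63 ± 0.25 (SD) at 5 genes higher in RNA and 0.56 ± 0.31 at 29 genes lower in RNA, a difference of 0.07 (permutation test over genes, two-sided, p = 0.635); after quantile normalization of the heights the means were 0.13 and 0.10. Across 11507 genes with both values, Pearson's r was 0.031 and Spearman's rho 0.031; genes are not independent replicates. Within 1 kb, the region at Ccl1 was the 1 region called in WT lists alone at a gene lower in RNA, and 0 regions called in cKO-labelled lists alone lay at called genes. Within 5 kb the difference was -0.085 and 4 genes lower in RNA had such a region; with the authors' genes, within 1 kb, 5 lower and 1 higher did, and 1 lower had a region called in cKO-labelled lists alone (Fisher's exact test, p = 1.0).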

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

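This result was chosen after the data were seen. Summed peaks on unplaced or unlocalized contigs, on chrM and on chrY were looked at. Sums on chrM and on chrY overlapped between groups (two-sided exact permutation test, p = 0.3 for chrM and p = 0.2 for chrY). The contigs were kept because every cKO-labelled value lay above every WT value. Peaks on these contigs are among the merged regions but were not compared apart from them. They summed to 6512.5 ± 316.7 tags per 10000000 in WT and 7605.3 ± 82.4 in cKO-labelled ATAC libraries (SD, n = 3 each). Every cKO-labelled value lay above every WT value (two-sided exact permutation test, p = 0.1, the smallest that 3 against 3 allows). The contigs were kept for this separation, so the choice fixed this p-value and it does not test for a difference. The mean covered length was 92.8 kb in WT and 105.1 kb in cKO-labelled libraries, and tags per kb overlapped, from 64.6 to 73.2 in WT and 68.6 to 75.1 in cKO-labelled libraries. No explanation was tested.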

How the results depend on the processing

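Alternatives outside the plan, chosen after seeing the data, were leaving out sex-linked genes, ranking peaks by tag count, other measures of region height, autosomes alone, regions called under all 4 scalings, the authors' genes in the ATAC and RNA comparison, and leaving out single ATAC libraries there. Tests on whole reads were not run, since the table does not give them, and the cause of each change below was not tested. The 37 RNA genes became 33 with the larger side turned to higher after quantile normalization, 1783 (also turned) with sample quality weights (7.43 for cKO replicate 1, at most 1.12 for the others), 6 with trimmed mean rescaling, 6 without the mean-variance trend, 526 by the authors' adjusted p and 122 with the replicate number as a replicate block; leaving out 1 library gave 1 to 150. The other settings gave 30 to 53. Of 21 named RNA genes past the threshold, Y-linked genes aside, none changed sign, and 1, Prcd, passed under every alternative; of 14 named ATAC regions 7 passed under every alternative and 4 changed sign. The 7 called lists became 0 with an estimated correlation and 5 to 11 when 1 library was left out, and without cKO replicate 2 more lists were higher (6) than lower (4). Fewer peaks per cKO-labelled library were found under every alternative, with exact p of 0.2 to 0.4. Regions in WT lists alone went from 2839 to 1022 and 1975 with top-scoring peaks (50 percent and all of the shortest list). They went to 618 with the tallest peaks, and to 3745 to 5595 with 1 library left out. Regions in cKO-labelled lists alone went from 321 to 825 and 520 with top-scoring peaks (50 percent and all of the shortest list) and to 426 to 1289. Heights called fell from 11223 to 3488 without subtraction, 2681 after quantile normalization, 3141 after cyclic loess and 1095 under all 4 scalings, each with more regions lower than higher; the replicate block gave 11098. The ATAC difference between RNA groups turned to -0.085 within 5 kb and -0.024 with the authors' genes and quantile normalization. Gata3 RNA was at -0.02 after quantile normalization and -0.08 to 0.14 with 1 library left out, Gclm RNA at -0.22 to 0.41. Per kb of peak, the regions at Mctp2, Cd44 and Trim41 turned to 0.31, 0.27 and 0.02, and the Nfe2l2 end turned to -0.02 after cyclic loess. With 3 libraries per group, a log2 change of 1 was recovered for 15 of 100 simulated RNA genes.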

Other observations

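Genes and regions in this paragraph were chosen after their values were seen. Prcd, the RNA with the largest fall among named genes past the threshold, also lost height at a region inside the gene (chromosome 11, 116656572 to 116658647), from 139.3 ± 37.1 tags per 10000000 in WT to 51.7 ± 2.2 in cKO-labelled libraries. The log2 change was -1.07 (adjusted p = 3.99e-05), -1.44 after quantile normalization and -0.79 per kb of peak, while the regions at both ends of Prcd changed sign between scalings. A region over Il2 (chromosome 3, 37118242 to 37131153) had its highest peak at 405.1 ± 47.5 and 190.5 ± 58.5 (log2 change -0.82, adjusted p = 0.0036), but its change was -0.11 for the sum of its peaks (adjusted p = 0.393) and -0.03 per kb of peak, and Il2 RNA changed by -0.23 (adjusted p = 0.502).

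Further lists stayed short of the threshold. Homing receptors and adhesion genes had a median of 0.29 over 24 members (camera adjusted p = 0.074). The list of p53 targets and apoptosis genes had a median of 0.20 over 25 (0.141). In it Bcl2a1d, a survival gene, fell by 0.85 (adjusted p = 0.0438). Among hypoxia genes, with a list median of -0.09, Higd1a had a log2 change of -1.25 (adjusted p = 0.0597) and Bnip3 of -1.21 (0.112). Stat4, a Th1 factor, was at 806.6 ± 110.0 and 410.9 ± 45.5 (adjusted p = 0.0613), and Phgdh, the first enzyme of serine synthesis, at 1291.0 ± 94.9 and 723.6 ± 22.2 (0.0546). Higd1a, Bnip3, Stat4 and Phgdh were past 0.05 as lower in the authors' own table (authors' adjusted p = 0.000213, 0.007, 0.000213 and 0.000104). Median, mean and camera differed in sign for plasma cell markers (median -0.23, mean 0.48, higher), for regulatory T cell genes (-0.01, 0.12, higher), for iron and heme genes (0.02, -0.05, lower), for B cell markers (0.03, -0.02, lower) and for markers of CD8 T, NK and gamma delta T cells (-0.03, 0.07, lower). Both fatty acid lists, interferon genes and T cell markers had positive medians of 0.03 to 0.07 with camera pointing lower, and none of these lists was called.

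The tests below, their predictions and their bounds were all written after the results were seen, the counts of splits included, although the counts of splits of the ATAC regions were planned. Bounds on the Cd4 stretch (500 bp and a log2 change of 2) were set with the values in view.

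Nfe2l2 RNA was higher in the cKO-labelled libraries. If Nfe2l2 is the deleted gene, which the labels do not state, a swap of the RNA labels needs NRF2 targets to be higher in the cKO-labelled libraries. Their median was -0.22, which runs against a swap. It lay at percentile 0.1 of matched random lists, but those were drawn without the correlation between genes. The adjusted p was 0.218 by fry and 0.637 by camera with an estimated correlation, so a swap stays open. A more active promoter may raise the transcript, but the ATAC change at the Nfe2l2 end ran from 0.79 down to -0.02 over the scalings, which leaves this open too. A transcript that is made but lacks a deleted part was not tested, since values per exon were not analysed here.

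The Cd4 stretch was taller in the cKO-labelled ATAC libraries. The tables argue against scaling, since the lowest change of the highest peak over the 4 scalings was 3.78; per kb of peak, with library medians subtracted, it was 1.93. A candidate explanation is extra copies of this DNA, such as a transgene that carries Cd4 sequence, though the labels name none: the cover had no gaps, its ends lay within 152 and 350 bp in the 3 libraries, and none of the 10 nearest regions changed by more than 1.07. Wider opening with more transcription stays open, with a Cd4 RNA change of 0.63 (adjusted p = 0.259).

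Y-linked transcripts were seen in the WT RNA libraries, with Kdm5d at a mean of 40.5 in WT and 0.9 in cKO-labelled libraries. Male cells in the WT samples may account for this: Xist in WT was 62.8% of its level in cKO-labelled libraries, with no overlap of values, which chance gives for 10% of genes. No ATAC list, WT or cKO-labelled, held a peak within 1 kb of Ddx3y, Eif2s3y, Kdm5d or Uty, while the tallest peaks at their X-linked counterparts had WT means of 98.1 to 226.2. In WT RNA, Ddx3y was at 131.9 against 2938.5 for Ddx3x, and Eif2s3y at 122.2 against 3157.5 for Eif2s3x. At these pairs, ATAC signal as low beside the X-linked counterpart would lie near the lowest WT peak, at 5.28 tags. The same holds for Kdm5d, at 40.5 against 1519.8 for Kdm5c. It does not hold for Uty, at 31.7 in WT RNA against 322 for Kdm6a. The tallest Kdm6a peaks had a WT mean of 226.2, so signal at Uty would lie above that lowest peak. Whether ATAC signal follows RNA in this way was not tested, so the lack of Y-linked peaks does not decide. Chromosome X had a median ATAC change of 0.218 after quantile normalization, against -0.055 to 0.071 on the autosomes, so a difference in sex between the ATAC groups stays open. Its median RNA change was 0.086, against -0.007 to 0.096. Whether sex sets the other RNA calls cannot be told apart from genotype, since both go with the same libraries, and 36 genes passed without the X-linked and Y-linked ones.

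The 6 libraries of an assay can be split in 10 ways, too few for a share under 0.05. For RNA genes the real split gave 37 and the highest other 1, so that 1 split, the real one, gave as many. For lists the real split gave 7 and the highest other 15, and 3 splits gave as many. The split of WT 1, cKO 1 and cKO 3 against the rest gave 3106 genes at an unadjusted p under 0.05 and 1 past the adjusted threshold, against 2188 and 37 for the real split. WT RNA libraries correlated with each other at 0.899 to 0.907 and with cKO-labelled ones at 0.901 to 0.928, and WT replicate 1 stood apart on the first principal component. For regions on 1 side alone, WT gave 2839 and the highest other split 975, and 1 split, the real one, gave as many as 2839. The cKO-labelled side gave 321, the highest other split 975, and 7 splits gave at least 321. For heights the real split gave 11223 and each of the other 9 splits 0, so that 1 split, the real one, gave as many.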
